A study of Homo sapiens with 16 samples.

How the data were processed

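RNA was measured in clones of HepG2, an established human liver cancer line, edited at PNPLA3 I148M and kept untreated or given palmitic acid. Per the labels' protocols, total RNA was taken with TRIzol and a column kit, ribosomal RNA was depleted, and stranded libraries were made with MGIEasy kits. The submitters' processing notes name Trimmomatic 0.38, RSEM 1.3.0, Bowtie2 and edgeR, and build hg38. The annotation, the gene filter, any rounding of counts and the vehicle given to the control cells are not given in the sources used here. The labels' protocol gives 48 h of palmitic acid for all treated libraries, while the labels of the single libraries run from 48 to 55 h in sample order; the protocol was taken, and no comparison used these hours.

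The deposited table holds a normalized signal for 16558 genes in 16 libraries. Every value was a whole multiple of 1 step per library (100% whole at a tolerance of 0.01 reads), so that the read counts behind the deposited signal could be recovered. Column totals ran from 961492 to 1052700, and TMM factors recomputed with edgeR differed from those in the table by at most 2.22e-16, so the deposited values are per-million counts with TMM scaling. Libraries held 9314342 to 15777669 reads and 15662 to 16206 detected genes, and the 10 most abundant genes took 8.36 to 13.4% of the reads. A gene's positions were taken from GENCODE on GRCh38, which placed 94.4% of the genes.

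Each library was divided by 1 common factor to give per-million units, which keeps the authors' scaling between libraries, and log2 of the value plus 0.5 was analysed. The 13095 genes with a mean of at least 1 unit were tested. The libraries form 6 groups of genotype and treatment, and n counts clones with 1 library per clone and treatment: 3 GG, 3 GC and 2 CC clones. The test was limma with a mean-variance trend on the 6 group means, two-sided, with 10 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05 over all tested genes, in 13 comparisons. These choices, the gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined; the design assumed normalized values, and tests on recovered reads by edgeR and DESeq2 served only as alternatives. R was 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

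The planned second fit took the clone as a replicate block and left 5 residual degrees of freedom; fold changes were equal in both fits, and errors and p-values differed. The control and treated library of a number come from the same clone, which is where the pairing comes from. In a check of this pairing, deviations from the group means correlated across genes at 0.523 to 0.857 within a clone, and in 8 of 8 clones the highest correlation was with the clone's own partner; with 2 CC clones both CC values are mirror images at 0.744. The block raised the count over genotypes to 2469 genes. Pearson correlations between replicates across genes were 0.929 to 0.975, and the lowest chi-square per degree of freedom between replicates was 25.3. Over all 120 pairs of libraries the lowest was 13.8, between the untreated libraries of GG clone 1 and GC clone 3, so no library is a copy of another. The treated library of CC clone 3 was nearer to that of GG clone 6 (20.4) than to its own control (43.4). The treated libraries of GC clone 3 and GG clone 1 were nearer to each other (17.0) than to their own controls (26.0 and 18.8). The other treated libraries were nearest to their own control. These distances include the palmitic acid change, which deviations from the group means leave out.

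For the gene lists, limma's camera with a preset correlation of 0.01 was run on 24 of 28 lists, adjusted over the lists of 1 comparison, and again with a correlation estimated per list. The lists hold 577 symbols, of which 499 were in the table, 11 of them under another symbol, and 448 were tested. Members were counted by limma over all genes and adjusted over the list alone. No mRNA of the mitochondrial genome passed the filter, and that list is not analysed here. Hepatocyte genes and metabolic genes are expressed by HepG2 itself; of the lists for other cell types, 5 stellate, 4 biliary, 3 macrophage and 2 endothelial genes passed the filter, which does not show what cells they came from.

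Named genes were those past adjusted p 0.05, with the same direction in all 8 clones (response over genotypes) or all clones of the genotype (response within a genotype), or with all libraries of a group above all of the other (between genotypes), a mean of at least 5 units in the higher group, and with a symbol that is not a placeholder, clone-derived name, antisense or small RNA. The filter on symbols also left out open-reading-frame names and ribosomal RNA precursors. Of these the 10 largest rises and 10 largest falls were taken over genotypes and up to 6 each way in other comparisons of levels. The rule adds up to 3 members of each list with the smallest p, every member of lists with at most 3 tested, and PNPLA3. The rule was applied to the planned fit with clone block for the palmitic acid responses, after the counts without block had been seen. Some genes that the rule takes are not reported here. Genes outside it are named as chosen after their values were seen.

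Alternatives were other pseudocounts, filters and scalings, a robust fit, a fit on the groups compared alone, the clone as a random effect, edgeR, DESeq2, and each library or clone left out. Recovery was tested on simulated data made from these libraries. With clone block, 85.1% of changes of 1.5-fold and 94.0% of changes of 2-fold were recovered over genotypes, with 7 false calls; without block the shares were 38.8% and 77.6%, with 0 false calls.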

Results

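Transcript levels were measured by RNA sequencing in 8 HepG2 clones. HepG2 is a human liver cancer line that keeps many hepatocyte functions. The clones were made by prime editing, which writes a chosen base change without a double-strand break, at the codon of PNPLA3 I148M. PNPLA3 encodes a lipid droplet protein that acts on triglyceride and retinyl ester, and I148M is its common variant associated with fatty liver disease. Clones were homozygous for the G allele, which encodes the I148M form (GG, 3 clones), heterozygous (GC, 3 clones) or homozygous for the C allele (CC, 2 clones). Which genotype the line held before editing is not stated here, and CC is the reference only by choice. Each clone gave 1 untreated control library and 1 library after palmitic acid at 250 µM, a saturated fatty acid used to load liver cells with lipid. The 16 libraries held 9314342 to 15777669 reads. The comparisons ask how the cells respond to palmitic acid, whether genotype goes with other transcript levels, and whether genotype goes with another response.

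PNPLA3 itself (ENSG00000100344.10, protein-coding, GRCh38 chromosome 22, 43923739 to 43964488, plus strand) was expressed at a low level, with 22 to 211 reads per library. In control cells its level was 4.93 ± 1.60 units in GG (SD, n = 3), 9.18 ± 2.40 in GC (SD, n = 3) and 7.64 ± 7.98 in CC (SD, n = 2), where units are per-million units. Under palmitic acid PNPLA3 was at 5.29 ± 2.68 units in GG, 10.7 ± 2.15 in GC and 8.61 ± 8.81 in CC. The 2 CC clones lay far apart, at 13.3 units in clone 1 and 1.99 in clone 3 without treatment. No genotype difference passed limma's test: the log2 differences in control were -0.15 ± 0.71 (SE) for GG against CC (adjusted p = 1.000), 0.69 ± 0.71 for GC against CC (0.999) and -0.84 ± 0.63 for GG against GC (0.805). Under palmitic acid the log2 difference between GG and GC was -1.02 ± 0.63 (adjusted p = 0.848). Over genotypes the log2 change with palmitic acid was 0.15 ± 0.11 with clone block (adjusted p = 0.348), upward in 6 of 8 clones. In the fit without block, single libraries turned its direction. The palmitic acid change there was -0.26 without the untreated library of CC clone 3 and -0.25 without the treated one of CC clone 1. Leaving out 1 library leaves its partner unpaired, while both CC clones themselves rose (13.3 to 14.8 and 1.99 to 2.39 units). In control, GC against CC was -0.54 without CC clone 3, and GG against CC was 1.08 without CC clone 1 and 0.052 without GG clone 6. The level of PNPLA3 does not check the genotype labels.

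**Figure D1:**
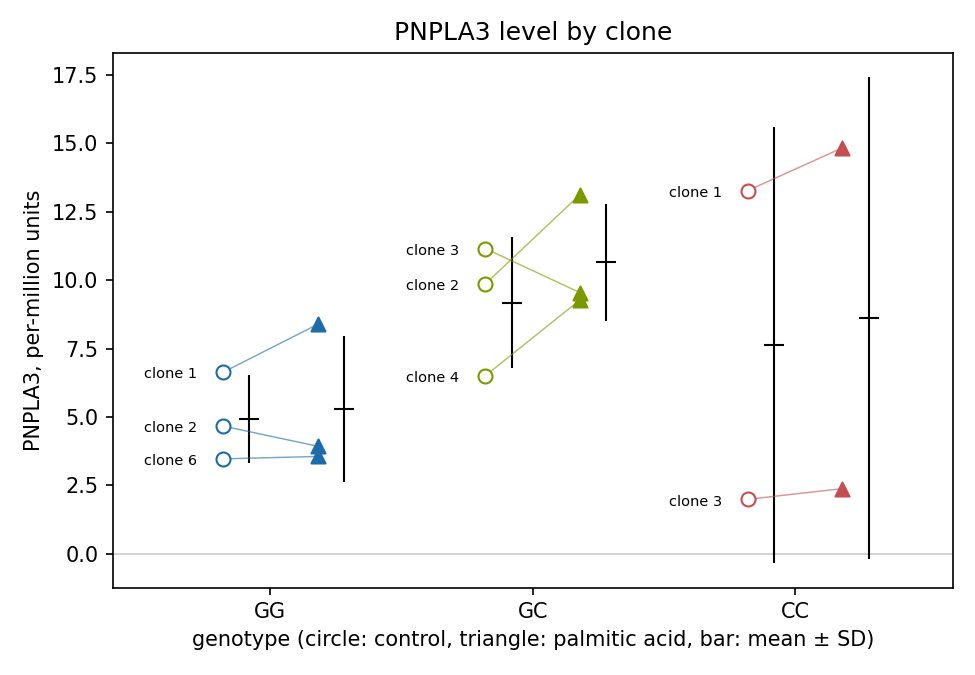
PNPLA3 level in per-million units for each clone, by genotype, with a line joining the control (circle) and the palmitic acid library (triangle) of a clone and bars at the mean ± SD. The CC clones lie at 13.3 and 1.99 units in control, outside the GG clones, which lie at 3.47 to 6.64 units.

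Clones of the same genotype differed widely. Of the sum of squares over the tested genes, 61.3% lay between clones within a genotype, 19.9% between genotypes, 8.17% between palmitic acid and control, 2.94% in the interaction and 7.61% in the residual. These shares rest on 5, 2, 1, 2 and 5 degrees of freedom, so per degree of freedom the first 3 lie much closer together. The first principal component held 30.3% and the second 19% of the variance. The log2 changes of CC clone 3 with palmitic acid had an SD of 0.567 across genes, against 0.311 to 0.404 in the other 7 clones.

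**Figure D2:**
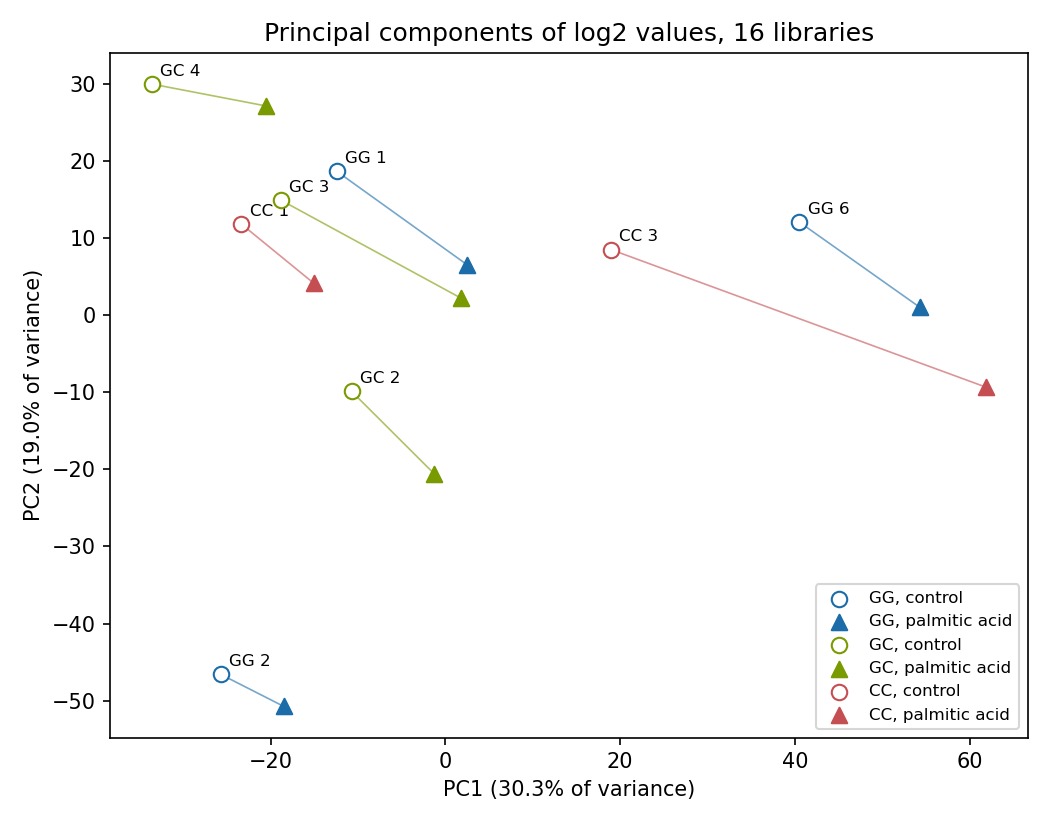
The 16 libraries on the first (30.3% of variance) and second (19%) principal component of the log2 values, with a line from the control (circle) to the palmitic acid library (triangle) of each clone. CC clone 3, whose log2 changes have an SD of 0.567, has the longest line.

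Palmitic acid moved many genes the same way in clones of all 3 genotypes. CPT1A, which carries long-chain fatty acids into mitochondria for oxidation (chromosome 11, 68754620 to 68844410), rose by 1.84 ± 0.17 on the log2 scale (SE, n = 8 clones, limma with clone block, adjusted p = 1.21e-04). Its level went from 9.83 ± 4.53 to 33.4 ± 23.4 units in GG (SD, n = 3), from 6.62 ± 5.01 to 23.1 ± 18.5 in GC (n = 3) and from 13.4 ± 13.1 to 63.6 ± 46.1 in CC (n = 2). FGB, the fibrinogen beta chain (chromosome 4, 154562956 to 154571086), had a log2 change of -1.55 ± 0.13 (adjusted p = 9.27e-05), from 1738 ± 595 to 815 ± 424 units in GG and from 1959 ± 463 to 678 ± 298 in GC. Other large rises were TMC7 (2.81 ± 0.22), the axonemal dynein DNAH17 (2.46 ± 0.17), the hyaluronan-degrading CEMIP (2.27 ± 0.19), the adhesion receptor ADGRG1 (2.16 ± 0.20), the proteoglycan BGN (1.94 ± 0.20), TNS1 (1.87 ± 0.40), the semaphorin and VEGF receptor NRP2 (1.79 ± 0.26) and MATN3 (1.67 ± 0.10). The other large falls were kininogen KNG1 (-2.08 ± 0.17), the pepsinogen PGC (-1.79 ± 0.15), the glutathione transferases GSTA1 (-1.76 ± 0.23) and GSTA2 (-1.46 ± 0.18), whose reads are hard to part, CUBN (-1.59 ± 0.21), the metalloproteinase MMP11 (-1.47 ± 0.12), the betaine carrier SLC6A12 (-1.37 ± 0.14), CD22 (-1.37 ± 0.15) and the glutamate carrier SLC1A2 (-1.33 ± 0.09). Each of these genes went the same way in 8 of 8 clones, as the rule for naming them required.

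Without the clone block, limma called 6 genes (3 up, 3 down; 1059 at an unadjusted p under 0.05), edgeR 2 and DESeq2 108. These 6 were MUC5AC (1.39 ± 0.16, adjusted p = 0.00516), the mitochondrial ribosomal protein MRPS23 (0.53 ± 0.07, 0.0292), the actin-severing CFL1 (0.52 ± 0.08, 0.0493), the coenzyme Q-binding COQ10A (-0.94 ± 0.11, 0.00516), MMP11 (-1.47 ± 0.22, 0.0452) and SLC6A12 (-1.37 ± 0.21, 0.0493). COQ10A went from 20.2 ± 4.08 to 10.4 ± 0.707 units in GG, from 21.8 ± 3.03 to 9.93 ± 1.11 in GC and from 19.4 ± 1.62 to 10.7 ± 0.0437 in CC. MUC5AC did not move the same way in all clones and is named after its value was seen. With the clone block, which compares each clone with itself, limma called 2469 genes, 1222 up and 1247 down, all 6 among them; 103 changed at least 2-fold. Of the 2469, 1493 (60.5%) went the same way in all 8 clones, against 13.6% of all tested genes and 0.781% by chance. The calls were made from these same changes and so favour agreeing signs, which makes the share of called genes no separate evidence. The count without block was 0 without the treated library of CC clone 3 and 82 without that of CC clone 1. With block it was 1254 without CC clone 3, 1448 without GC clone 3, 1538 without GG clone 1 and 3753 without CC clone 1.

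**Figure D3:**
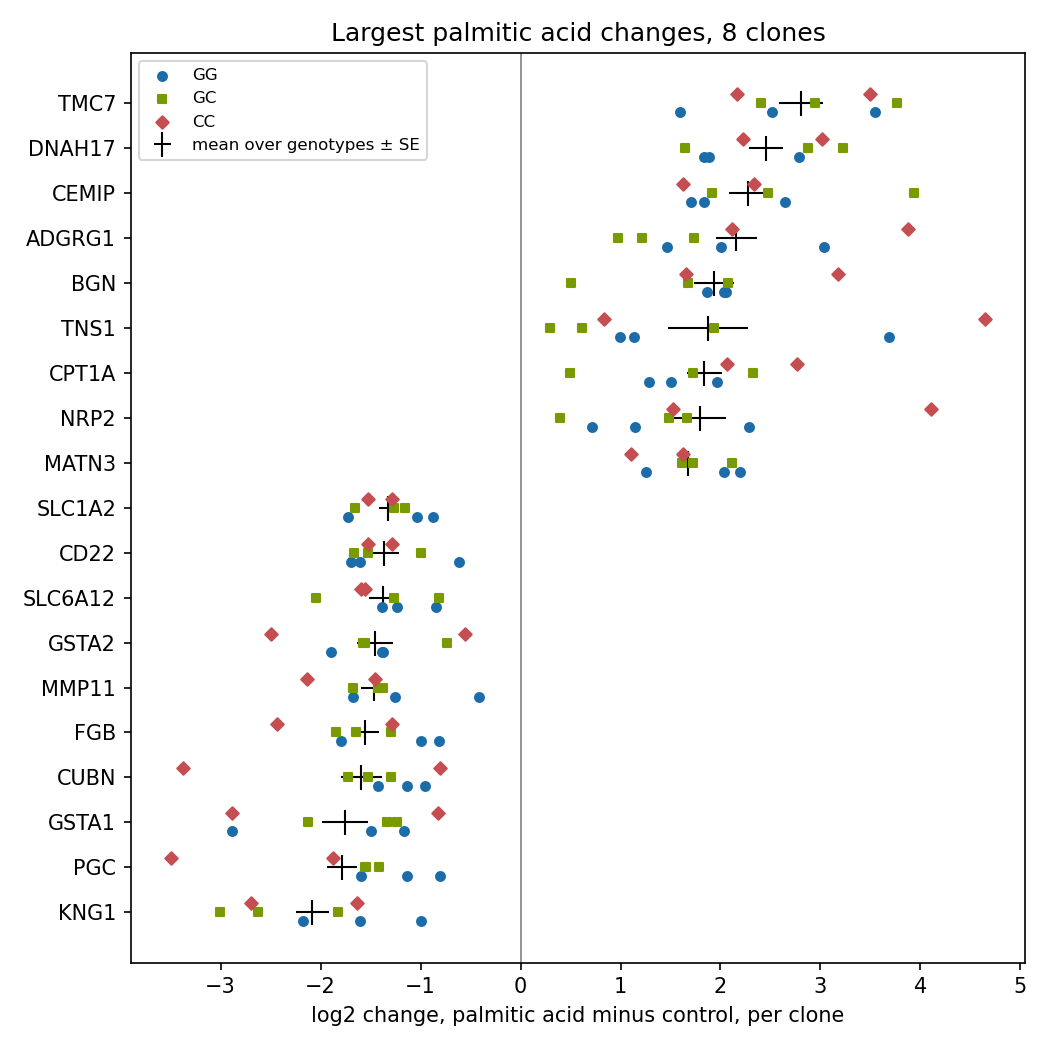
Log2 change of each clone (palmitic acid minus control) for the genes with the largest rises and falls named in the text, with the mean over genotypes ± SE from limma with clone block. The rule for named genes puts every point of a gene on the same side of 0, from TMC7 (mean 2.81) to KNG1 (mean -2.08).

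Camera at its preset correlation called the hepatocyte, apolipoprotein and cell cycle lists downward under palmitic acid. Of 24 hepatocyte identity and plasma protein genes, 0 rose, 12 fell and 12 did not pass limma's test with clone block (15 down adjusted over the list alone), with a median of -0.31: FGB, the fibrinogen gamma chain FGG (-1.13 ± 0.13) and the retinol carrier RBP4 (-0.68 ± 0.06) fell. Camera gave an adjusted p = 5.87e-07 for the list, and adjusted p = 0.442 with an estimated correlation. Of 18 apolipoprotein and lipoprotein assembly genes, 8 fell (12 down adjusted over the list alone; median -0.30), among them APOA5, which promotes plasma triglyceride clearance (-1.01 ± 0.17), APOM (-0.56 ± 0.10) and APOA1 of high-density lipoprotein (-0.45 ± 0.10). Camera's adjusted p was 1.81e-05, with adjusted p = 0.442 with an estimated correlation. Of 30 cell cycle genes, 9 fell (11 down adjusted over the list alone; median -0.24), among them the mitotic kinesin KIF20A (-0.51 ± 0.11), the kinase AURKB (-0.46 ± 0.10) and the topoisomerase TOP2A (-0.37 ± 0.09). The camera adjusted p was 5.14e-06, and adjusted p = 0.670 with an estimated correlation.

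Camera at its preset correlation called the glycolysis, oxidative stress and matrix lists upward. Of 22 glycolysis and hypoxia genes, 9 rose and 0 fell (10 up adjusted over the list alone; median 0.21), among them the glucose carrier SLC2A1 (1.09 ± 0.13), the hexokinase HK1 (0.52 ± 0.07) and the pyruvate kinase PKM (0.53 ± 0.09). The camera adjusted p was 5.14e-06, and adjusted p = 0.442 with an estimated correlation. Of 19 targets of NRF2, the oxidative stress regulator, 9 rose and 0 fell (10 up adjusted over the list alone; median 0.24), among them the aldo-keto reductase AKR1B10 (1.09 ± 0.16) and the export pump ABCC2 (0.30 ± 0.05). Camera gave 5.14e-06, and adjusted p = 0.442 with an estimated correlation. Of 14 extracellular matrix and TGF-beta response genes, 6 rose and 1 fell (8 up and 1 down adjusted over the list alone; median 0.44): the cytokine TGFB1 (1.054 ± 0.119) and the matrix protein SPARC (0.81 ± 0.09) rose, and ACTA2, smooth muscle actin, fell by 0.56 ± 0.12. Camera gave 7.86e-04, and adjusted p = 0.442 with an estimated correlation.

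Lists of stress, autophagy and cell death were called upward as well, with smaller medians. Of 24 autophagy and lysosome genes, 8 rose and 1 fell (13 up and 2 down adjusted over the list alone; median 0.16): the autophagy receptor SQSTM1 (0.84 ± 0.13) and the lysosomal galactosidase GLA (0.35 ± 0.08) rose, while TFEB, the transcription factor of lysosomal genes, fell by 0.69 ± 0.09. The camera adjusted p was 0.00169, and adjusted p = 0.537 with an estimated correlation. Of 23 integrated stress response genes, targets of ATF4 and CHOP, 6 rose and 1 fell (10 up and 2 down adjusted over the list alone; median 0.19), with the cytokine GDF15 at 1.16 ± 0.21, the mTORC1 inhibitor DDIT4 at 0.61 ± 0.13 and ATF3 at 0.58 ± 0.12. Camera called it with the block only (adjusted p = 0.00410 with block, 0.109 without, and adjusted p = 0.827 with block and an estimated correlation). Of 19 apoptosis genes, 4 rose and 0 fell (6 up adjusted over the list alone; median 0.13): those with the smallest p were the survival factor MCL1 (0.59 ± 0.11), the gasdermin DFNA5 (0.56 ± 0.09) and the caspase inhibitor XIAP (0.40 ± 0.05), so that both survival and death genes were among them. The camera adjusted p was 0.0195, and adjusted p = 0.442 with an estimated correlation. In all, camera called 9 of 24 lists with block and 8 without, and 0 with an estimated correlation in any of the 13 comparisons.

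**Figure D4:**
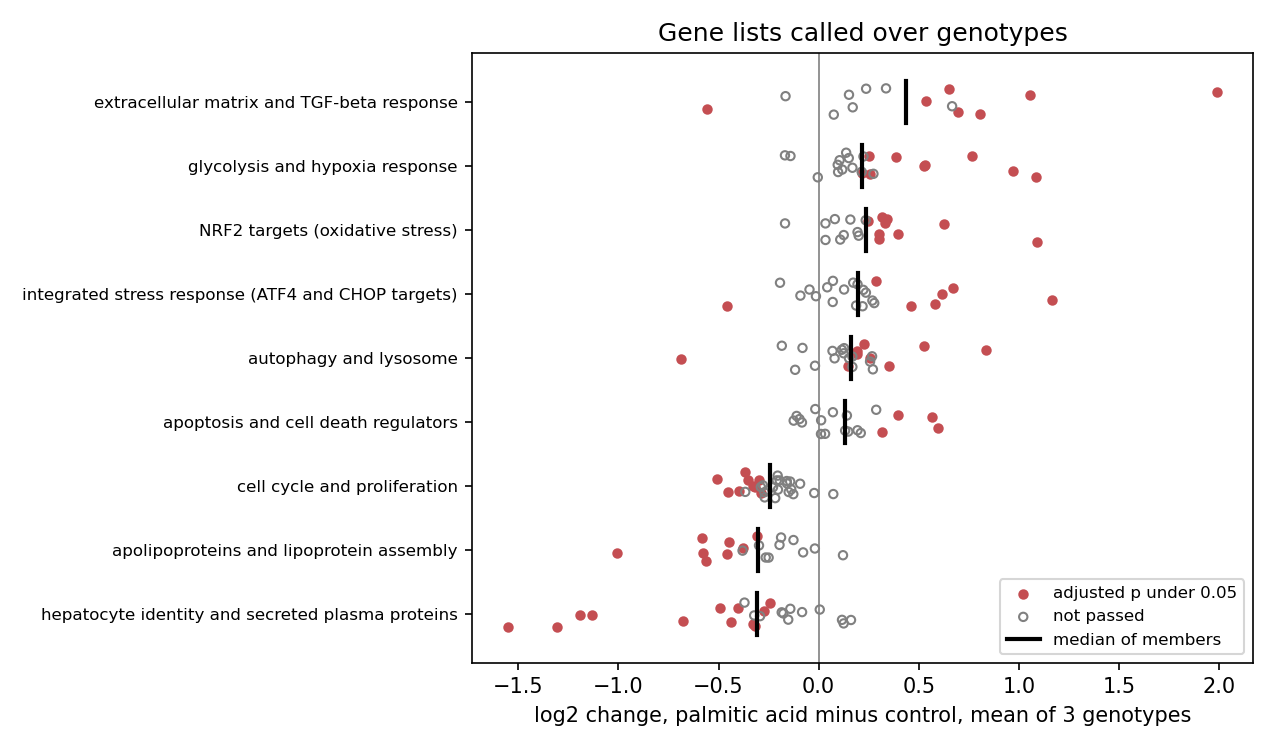
Log2 change of each tested member (palmitic acid minus control, mean of the 3 genotypes) for the 9 lists called by camera, with filled points for members past adjusted p 0.05 with clone block and a bar at the median. Medians run from -0.31 for hepatocyte genes to 0.44 for matrix and TGF-beta genes.

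Over genotypes camera called none of the lists of fatty acid, lipid droplet, cholesterol and bile acid genes, though single members changed. Of 25 PPAR-alpha and fatty acid oxidation genes, 5 rose and 5 fell (5 up and 7 down adjusted over the list alone; median -0.03, mean 0.08, camera adjusted p = 0.976). CPT1A, the lipid droplet coat gene PLIN2 (1.25 ± 0.15) and ACADVL of very-long-chain oxidation (0.41 ± 0.05) rose. PLIN2 went from 257 ± 92.7 to 489 ± 166 units in GG, from 168 ± 14.6 to 392 ± 45.2 in GC and from 169 ± 52.4 to 683 ± 666 in CC. Chosen after their values were seen, CREB3L3 rose (0.95 ± 0.15), while the lipoprotein lipase inhibitor ANGPTL4 (-1.13 ± 0.17) and the receptor PPARA (-0.37 ± 0.09) fell. Of 21 lipid droplet and triglyceride genes, 3 rose and 5 fell (5 up and 5 down adjusted over the list alone; median 0.05, camera adjusted p = 0.910): the triglyceride synthase DGAT1 (-0.73 ± 0.08) and the carboxylesterase CES1 (-0.64 ± 0.07) fell, as did PLIN5 (-1.24 ± 0.21), named after its value was seen. Of 16 fatty acid synthesis genes, 3 rose and 3 fell (3 up and 4 down adjusted over the list alone; camera adjusted p = 0.890): ACSL3, an acyl-CoA synthetase, rose (0.38 ± 0.09), and the acyltransferase GPAM (-0.46 ± 0.07) and the carbohydrate-sensing factor MLXIPL (-0.52 ± 0.11) fell. Of 24 cholesterol synthesis genes, targets of SREBP2, 4 rose and 1 fell over all genes and adjusted over the list alone (median 0.12, camera adjusted p = 0.0725): DHCR7, of a late step of cholesterol synthesis, rose (0.41 ± 0.09). Of 12 bile acid genes, 4 rose and 3 fell over all genes and over the list alone (median -0.05, camera adjusted p = 0.974), with the nuclear receptor NR0B2 up (0.76 ± 0.11) and the phospholipid pump ABCB4 down (-0.43 ± 0.07).

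Other lists were not called either. Of 14 genes at other fatty liver risk loci, 2 rose and 4 fell (5 down adjusted over the list alone; median -0.11, camera adjusted p = 0.142), with TRIB1 at 0.99 ± 0.14 and ERLIN1 at -0.34 ± 0.05. Of 11 tested neighbours of PNPLA3 on chromosome 22, 1 rose, the outer mitochondrial membrane protein TSPO (0.66 ± 0.12; median 0.03, camera adjusted p = 0.558). Of 20 p53 targets, 4 rose and 2 fell (5 up and 2 down adjusted over the list alone; median 0.08, adjusted p = 0.234), with the cyclin kinase inhibitor CDKN1A at 0.33 ± 0.06 and TIGAR at 0.32 ± 0.07. Of 21 ER chaperone genes, 2 rose and 2 fell (median 0.03, adjusted p = 0.912): EDEM1 of ER-associated degradation rose (0.41 ± 0.07), and PDIA4 (-0.30 ± 0.06) and CALR (-0.24 ± 0.06) fell. Of 34 nuclear-encoded oxidative phosphorylation genes, 1 rose, NDUFV2 (0.28 ± 0.06), and 1 fell, NDUFA2 (-0.24 ± 0.06; median 0.02, adjusted p = 0.664). Of 15 interferon-stimulated genes, 1 rose and 4 fell (median 0.04, mean -0.07, adjusted p = 0.910), with IFITM1 at 0.46 ± 0.06 and IFIT1 at -0.86 ± 0.13. Of 9 NF-kB genes, 1 rose, RELB (0.76 ± 0.15), and 1 fell, SOD2 (-0.16 ± 0.05; median 0.21, adjusted p = 0.0764). The metallothionein MT2A was at 1.01 ± 0.33 (adjusted p = 0.0547), MT1E at 0.27 and MT1X at -0.16, with 0 of 3 called over all genes and 1, MT2A, adjusted over the list alone. For the lists of neighbours, ER chaperones, oxidative phosphorylation, interferon and NF-kB genes, the counts adjusted over the list alone equal those over all genes.

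Genes listed as markers of other liver cell types moved singly in these HepG2 clones. Of 5 stellate and fibroblast genes, TAGLN (1.25 ± 0.30) and PDGFRB (1.12 ± 0.30) rose and ACTA2 fell (median 0.24, camera adjusted p = 0.773). Of 4 biliary genes 0 were called by limma, with KRT19 at 0.37 ± 0.17 (-0.041 without the CC clones) and EPCAM at 0.13 (median 0.03, adjusted p = 0.912). Of 14 oncofetal genes, SOX4 rose (0.64 ± 0.09) and the fetal plasma protein AFP fell (-0.54 ± 0.12; median 0.04, adjusted p = 0.773). CD14 of macrophages fell (-1.03 ± 0.20), with LYZ at 0.16 and CD68 at -0.08, and of the endothelial genes PECAM1 fell (-0.59 ± 0.12) and LYVE1 was at 0.64 ± 0.23 (adjusted p = 0.0764), past the threshold only when adjusted over the list alone. For the stellate, biliary and oncofetal lists, the counts adjusted over the list alone equal those over all genes.

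Within each genotype many of these genes were again among the largest changes. The rule for named genes asks for the same direction in all clones of the genotype. In GG clones, with clone block, TMC7 (2.55 ± 0.35), MATN3 (1.83 ± 0.17, limma adjusted p = 0.00334), DNAH17, ADGRG1, CEMIP and BGN rose most, and GSTA1, KNG1, GSTA2, the iron hormone HAMP (-1.28 ± 0.25, adjusted p = 0.0420), SLC1A2 and FGB fell most. In GC clones TMC7 (3.04 ± 0.35), CEMIP, DNAH17, MATN3 and GDF15 (1.74 ± 0.34, adjusted p = 0.0361) were among the largest rises, and KNG1 (-2.49 ± 0.27), FGB, CUBN, PGC, MMP11 and the betaine-homocysteine methyltransferase BHMT (-1.40 ± 0.28) fell most. In CC clones MUC5AC (4.12 ± 0.32, adjusted p = 5.64e-04), ADGRG1 (3.00 ± 0.40), TMC7, NRP2, DNAH17 and CPT1A (2.42 ± 0.34) rose most. The falls there were the read-through GPR75-ASB3 (-3.15 ± 0.43), PGC (-2.69 ± 0.30), the peroxisomal AGXT (-2.20 ± 0.26), KNG1, CUBN and complement C8B (-2.01 ± 0.35). With block limma called 110 genes in GG (75 up, 35 down), 202 in GC (115 up, 87 down) and 301 in CC (111 up, 190 down). Without block limma called 0, 0 and 1 (223, 265 and 276 at an unadjusted p under 0.05), the 1 being MUC5AC (adjusted p = 6.73e-05). These 3 counts at an unadjusted p lie below the share of 0.05 of the 13095 tested genes that chance alone is expected to give. EdgeR called 0, 0 and 0 and DESeq2 1, 2 and 0. Leaving out 1 clone gave 0 (GG clone 1) to 24 (GG clone 2) blocked calls in GG, 2 (GC clone 4) to 107 (GC clone 2) in GC, and 13 (CC clone 3) or 2082 (CC clone 1) in CC.

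The genotypes shared more calls than independent lists would. The 3 lists use 1 error per gene from all clones, so a gene with a small error is favoured in each. Independence is therefore only a rough reference. GG and GC shared 42 rising and 25 falling genes, where independent lists would share 0.659 and 0.233. GG and CC shared 41 rising and 25 falling genes (independent lists 0.636 and 0.508), and GC and CC 42 rising and 48 falling (0.975 and 1.26). Across genes, which are not independent replicates, the log2 changes correlated at 0.674 between GG and GC, 0.585 between GG and CC and 0.612 between GC and CC. Of the hepatocyte list, 2 members fell in GG (median -0.14, camera adjusted p = 0.0119), 4 in GC (-0.20, 4.96e-05) and 10 in CC (-0.58, 1.63e-11), by limma with block. Adjusted over the list alone, 4, 6 and 17 fell, and with an estimated correlation the hepatocyte list had adjusted p = 0.846, adjusted p = 0.464 and adjusted p = 0.557. The larger fall in CC rests mostly on CC clone 3. Without that clone its difference from GG shrank and that from GC reversed, as given below. Camera called 7 lists in GG, 11 in GC and 8 in CC with block and 4, 11 and 6 without. Leaving out CC clone 3, it called 8, 12 and 1 without block. In CC the cholesterol synthesis list was called as well (median 0.32, adjusted p = 0.00184 without block, and adjusted p = 0.637 with an estimated correlation), and its mean was -0.082 without CC clone 3.

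In control cells limma called no single gene between the genotypes. Camera called some lists at its preset correlation and 0 with an estimated one. Cell cycle genes had a median log2 difference of -0.47 in GG against CC (camera adjusted p = 2.00e-05; adjusted p = 0.951 with an estimated correlation), with MCM5 at -0.53 ± 0.37 and E2F1 at -0.49 ± 0.35, and of -0.38 in GC against CC (9.56e-04; adjusted p = 0.794 with an estimated correlation). Cholesterol synthesis genes had a median of 0.32 in GC against CC (4.30e-04; adjusted p = 0.794 with an estimated correlation), with DHCR7 at 0.83 ± 0.33 and the regulator SREBF2 at 0.63 ± 0.26. The other lists called for GC against CC were fatty acid synthesis (0.25, adjusted p = 0.0161), NRF2 targets (0.29, 0.0161), p53 targets (-0.32, 0.0161) and PPAR-alpha targets (0.18, 0.0286), each with adjusted p = 0.794 with an estimated correlation. In GG against GC, p53 targets had a median of 0.40 (9.69e-04; adjusted p = 0.679 with an estimated correlation), with TIGAR at 0.97 ± 0.28 and the p53 ligase MDM2 at 0.66 ± 0.22. Fatty acid synthesis genes were at -0.34 there (0.00948), with the elongase ELOVL6 at -0.60 ± 0.17, and apolipoproteins at -0.32 (0.0459), both with adjusted p = 0.798 with an estimated correlation. Oxidative phosphorylation genes were at 0.08 in GG against CC (0.0192; adjusted p = 0.951 with an estimated correlation). The neighbours of PNPLA3 were not called (camera adjusted p = 0.943, 0.756 and 0.920); among them TSPO was at 0.99 ± 1.08 in GG against CC, and at -0.99 without the untreated library of CC clone 1. Without CC clone 3 the cell cycle medians were -0.94 in GG against CC and -0.90 in GC against CC. In GG against CC this difference lies against CC clone 1, and against CC clone 3 it is nearly absent. With CC as the mean of 2 clones, the list mean went from -0.46 with all clones to -0.90 without CC clone 3. The mean of the cholesterol list in GC against CC was then -0.32 (camera adjusted p = 0.0219; adjusted p = 0.745 with an estimated correlation). The other lists against CC lost their call then: fatty acid synthesis (mean -0.10, adjusted p = 0.747), NRF2 targets (0.180), p53 targets (0.104) and PPAR-alpha targets (0.288) in GC against CC, and oxidative phosphorylation (mean -0.069, adjusted p = 0.360) in GG against CC.

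Adjusted over the list alone, limma called a few list members between genotypes in control. IFI27, an interferon-induced gene, was at 3.76 ± 1.79 units in GC (SD, n = 3), 0.574 ± 0.319 in GG and 0.590 ± 0.745 in CC, a log2 difference of 2.08 ± 0.49 for GC against CC and -1.96 ± 0.43 for GG against GC. NFKBIA, the inhibitor of NF-kB, was at 33 ± 7.66 units in GC, 75.7 ± 8.14 in GG and 67.0 ± 3.92 in CC. The glucokinase regulator GCKR, at a fatty liver risk locus, was at 20.9 ± 5.11 units in GC and 7.85 ± 2.88 in CC (log2 difference 1.37 ± 0.38), and the oncofetal RNA-binding LIN28B differed by 1.04 ± 0.28 for GG against GC. Over all genes none of these passed: the limma adjusted p for IFI27 was 0.999 for GC against CC and 0.532 for GG against GC, and for NFKBIA 0.519 for GG against GC. With each clone left out in turn, only NFKBIA for GG against GC kept its call over the list alone (highest limma adjusted p = 0.0258, without GC clone 3). For GC against CC the limma adjusted p over the list alone reached 0.328 for IFI27 (log2 difference 1.32), 0.564 for GCKR and 0.187 for NFKBIA, each without CC clone 1. For GG against GC it reached 0.0824 for IFI27 (without GG clone 1) and 0.184 for LIN28B (without GG clone 6). By limma 0 genes were called in control for GG against CC, GC against CC and GG against GC, with 156, 408 and 871 at an unadjusted p under 0.05. Chance alone is expected to put a share of 0.05 of the 13095 tested genes there, which is more than 156 and 408 and fewer than 871. EdgeR called 0, 0 and 0, and DESeq2 0, 2 and 20. On simulated data 23.9% of 2-fold and 69.7% of 4-fold differences were recovered for GG against CC with 17 false calls, and for GG against GC 29.9% and 74.2% with 20, so that these comparisons make more false calls than the threshold states. Their fit counts both libraries of a clone as independent, although libraries of a clone correlated at 0.742 (consensus over genes).

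Under palmitic acid camera called the hepatocyte list upward in GG and GC clones against CC clones, while 0 of its members passed limma's test. The median log2 difference was 0.35 for GG against CC (camera adjusted p = 2.10e-06; adjusted p = 0.825 with an estimated correlation), with the asialoglycoprotein receptor ASGR1 at 0.75 ± 0.24, and 0.31 for GC against CC (0.00351; adjusted p = 0.651 with an estimated correlation), with ASGR1 at 0.81 ± 0.24. Cell cycle genes were at -0.42 in GG against CC (2.35e-05; adjusted p = 0.845 with an estimated correlation) and -0.46 in GC against CC (0.00351; adjusted p = 0.802 with an estimated correlation), with the ribonucleotide reductase RRM2 at -1.11 ± 0.74 and CCNE2 at -0.53 ± 0.29. PPAR-alpha targets were at 0.20 in GG against CC (0.00962; adjusted p = 0.845 with an estimated correlation) and 0.20 in GC against CC (0.0205; adjusted p = 0.651 with an estimated correlation). For GC against CC, oxidative phosphorylation genes (0.17, adjusted p = 0.0272) and apolipoproteins (0.28, 0.0307) were called too, both with adjusted p = 0.651 with an estimated correlation; APOA5 was at 1.66 ± 0.66 and NDUFB5 at 0.71 ± 0.19. In GG against GC, fatty acid synthesis genes were at -0.28 (0.00741) with ELOVL6 at -0.58 ± 0.17, and p53 targets at 0.27 (0.00741) with TIGAR at 0.82 ± 0.28, both with adjusted p = 0.665 with an estimated correlation. Cholesterol synthesis genes were at -0.28 there (0.0179; adjusted p = 0.689 with an estimated correlation), with SREBF2 at -0.52 ± 0.23. The neighbours of PNPLA3 were not called (camera adjusted p = 0.690, 0.347 and 0.467). Adjusted over the list alone, NUP50 was lower in GC than in CC (-0.56 ± 0.15) and TTLL1 lower in GG than in GC (-1.003 ± 0.273), but over all genes limma's adjusted p was 0.580 and 0.818. Adjusted over the list alone, IFI27 (2.11 ± 0.49), GCKR (1.64 ± 0.38) and the NF-kB inhibitor TNFAIP3 (1.15 ± 0.35) were higher in GC than in CC and NFKBIA (-0.86 ± 0.28) lower, and IFI27 (-2.10 ± 0.43) was lower and NFKBIA (0.98 ± 0.25) and LIN28B (0.99 ± 0.28) higher in GG than in GC; over all genes 0 of these passed. With each clone left out in turn, only IFI27 for GG against GC kept its call over the list alone (highest limma adjusted p = 0.0359, without GG clone 6). For GC against CC the limma adjusted p over the list alone reached 0.0584 for IFI27 and 0.177 for NUP50 (without GC clone 3), 0.152 for GCKR (without CC clone 3), 0.167 for TNFAIP3 (without GC clone 4) and 0.194 for NFKBIA (without CC clone 1). For GG against GC it reached 0.160 for TTLL1 (without GG clone 2), 0.117 for NFKBIA (without GG clone 6) and 0.248 for LIN28B (without GG clone 1). Without CC clone 3 the mean of the hepatocyte list was -0.051 in GG against CC (camera adjusted p = 0.874) and -0.18 in GC against CC (0.855), so this call rests on that clone. The cell cycle medians were then -1.10 and -1.07. These differences rest on CC clone 1: with CC a mean of 2 clones, they point the other way against CC clone 3. In GG against CC the list mean went from -0.46 with all clones to -1.11 without CC clone 3. In GC against CC it went from -0.44 to -1.09 without CC clone 3. Other calls lost then were PPAR-alpha targets in GG against CC (0.607) and GC against CC (0.362), and in GC against CC oxidative phosphorylation (0.457) and apolipoproteins (mean 0.0495, adjusted p = 0.938).

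Limma called 1 gene for GG against CC under palmitic acid, MUC5AC (-4.22 ± 0.28, adjusted p = 1.60e-05), 1 for GC against CC, again MUC5AC (-4.16 ± 0.28, adjusted p = 1.92e-05), and 0 for GG against GC, with 241, 1096 and 789 at an unadjusted p under 0.05. A share of 0.05 of the 13095 tested genes, expected by chance alone, is more than 241 and fewer than 1096 and 789. EdgeR called 0 in each, and DESeq2 1, 21 and 21.

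The response to palmitic acid was compared between genotypes by the interaction. Camera called a difference for the hepatocyte list, of which 0 members passed limma's test, between GG and CC (median difference 0.45, camera adjusted p = 4.58e-06; adjusted p = 0.854 with an estimated correlation) and between GC and CC (0.34, 3.80e-04; adjusted p = 0.523 with an estimated correlation). With errors from the fit with clone block, ASGR1 differed by 0.71 ± 0.20 and 0.64 ± 0.20, and the iron carrier TF by 0.87 ± 0.28 in GG against CC. Apolipoproteins differed by 0.30 in GG against CC (0.0119; adjusted p = 0.854 with an estimated correlation), with APOA5 at 1.16 ± 0.44. Cholesterol synthesis genes differed by -0.32 in GG against CC (0.00235; adjusted p = 0.893 with an estimated correlation) and by -0.24 in GC against CC (0.00860; adjusted p = 0.824 with an estimated correlation). Between GG and GC, oxidative phosphorylation genes differed by -0.10 (0.0196; adjusted p = 0.928 with an estimated correlation), with UQCRB at -0.33 ± 0.15. Adjusted over the list alone with block, the members called were UQCRB (-0.85 ± 0.17) and ABCB4 (0.63 ± 0.17) for GG minus CC and KRT19 (-1.47 ± 0.43) for GC minus CC; over all genes limma's adjusted p was 0.797, 0.797 and 0.911. Over the list alone these calls were lost without CC clone 3 for UQCRB (limma adjusted p = 0.156) and ABCB4 (0.42, adjusted p = 0.567), and without GC clone 4 for KRT19 (adjusted p = 0.0742). With clone block, camera also called the integrated stress response in GC against CC (0.21, adjusted p = 0.0436, and adjusted p = 0.767 with an estimated correlation). Between GG and GC the block also called the integrated stress response (-0.18, 0.00366), ER chaperones (0.12, 0.00654), hepatocyte genes (0.12, 0.0353) and NF-kB genes (-0.11, 0.0353), each with adjusted p = 0.875 with an estimated correlation. Without CC clone 3 the hepatocyte mean was 0.086 in GG against CC and -0.051 in GC against CC, the apolipoprotein mean -0.035 and the cholesterol means 0.094 and 0.15, and camera called none of these with or without block. For GG minus CC and GC minus CC it then called 2 and 5 other lists without block and 6 and 5 with it, and 0 in each with an estimated correlation. In the fit without block, leaving out a single CC library turned the direction of TF (-0.41 without the treated library of CC clone 3) and of APOA5 (-0.11, the same library). The untreated library of that clone is then left unpaired.

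MUC5AC, a gel-forming mucin of mucous epithelium (GRCh38 chromosome 11, 1157953 to 1201138, plus strand), was the 1 gene whose response differed by limma between GG and CC (-4.12 ± 0.40, adjusted p = 0.00145; 0.00809 with block) and between GC and CC (-4.06 ± 0.40, 0.00173; 0.00943 with block). For GG against GC 0 genes were called, with and without block. At an unadjusted p under 0.05 there were 52, 28 and 26 genes without block and 768, 613 and 229 with it. Of these counts only 768 exceeds a share of 0.05 of the 13095 tested genes, which chance alone is expected to give. EdgeR called 0 in each, with and without block, and DESeq2 0 in each. MUC5AC had 109 and 94 reads in the treated libraries of CC clones 1 and 3 (7.67 and 10.2 units), 1 read in the untreated library of CC clone 3, 1 in the treated library of GC clone 2 and 0 in the other 12 libraries, so its fitted fold changes depend on the pseudocount. Under a rule set after the data were seen, 13 genes were at least 5 times above the highest other library in both treated CC libraries. Among them CEACAM6 had 67 and 28 reads, MUC1 50 and 28, the trefoil peptides TFF2 32 and 18 and TFF1 22 and 19, and REG4 22 and 18, while no other library held more than 4 reads of any of the 13. MUC5AC alone of the 13 passed the filter on level.

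**Figure D5:**
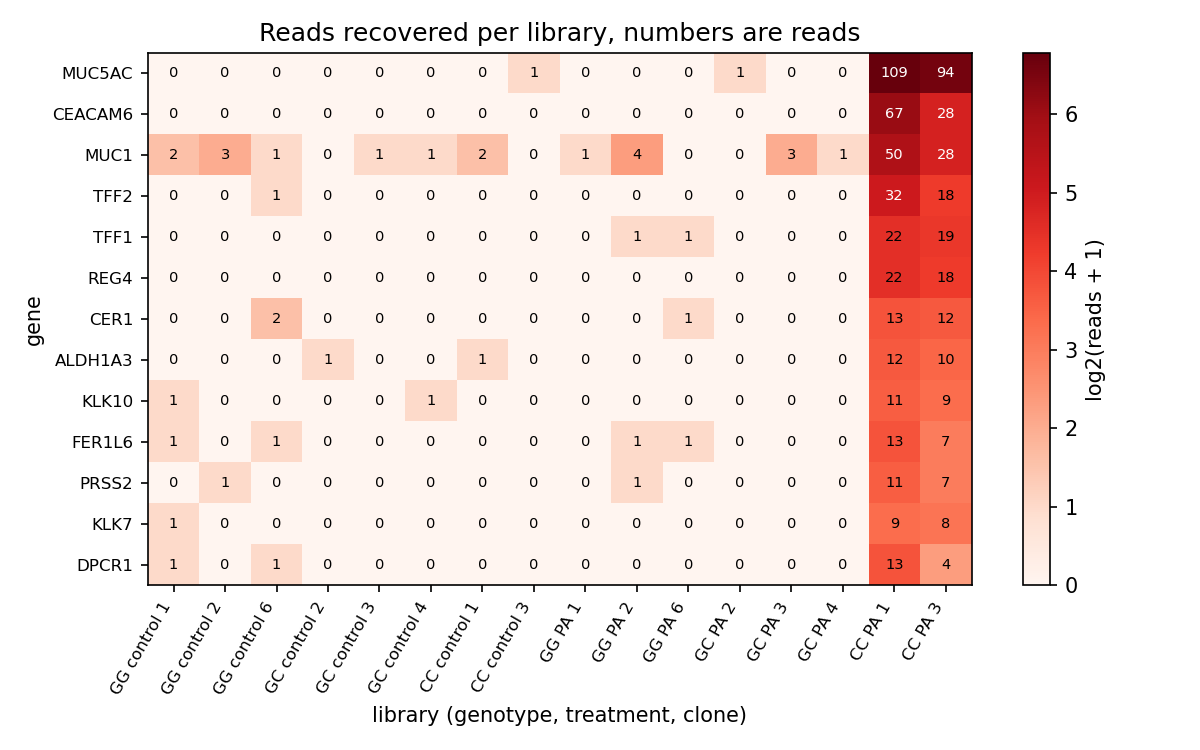
Reads of 13 genes in each of the 16 libraries, with color on a log2(reads + 1) scale. The treated libraries of CC clones 1 and 3 hold 384 and 262 reads of these genes in all, and no other library holds more than 4 of any gene.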

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

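Of the tests in this part, those on the ratio between the 2 libraries, on the GC libraries, on CC clone 1, on the partner libraries of a clone and on chromosome medians were chosen only after the result was seen.

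The response of MUC5AC to palmitic acid differed between genotypes by the interaction, with a log2 difference of -4.12 for GG minus CC (limma adjusted p = 0.00145) and -4.06 for GC minus CC (0.00173). Gene lists differed in the same way, by camera: hepatocyte genes by a mean of 0.48 for GG minus CC (4.58e-06) and 0.34 for GC minus CC (3.80e-04), cholesterol synthesis genes by -0.29 (0.00235) and -0.23 (0.00860), apolipoproteins by 0.33 for GG minus CC (0.0119) and oxidative phosphorylation genes by -0.086 for GG minus GC (0.0196). None of the list differences passed with an estimated correlation, where the lowest adjusted p was 0.854 for GG minus CC, 0.491 for GC minus CC and 0.928 for GG minus GC. Both MUC5AC calls were lost with a pseudocount of 0.1, in a fit on only the groups compared, by edgeR and by DESeq2.

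In both treated CC libraries 13 genes, several of them of mucous epithelium and led by MUC5AC at 7.67 and 10.2 units, stood at least 5 times above every other library. RNA of a mucous epithelial cell type carried into these 2 libraries may be the source: of 53 markers listed before they were looked up, 32 were in the table, and 5 of these (PIGR, TSPAN8, MUC17, LGALS4 and GALNT6, named after their values were seen) were above all 14 other libraries in both, against a mean of 0.299 and a highest count of 5 in 10000 level-matched random sets (share 2e-04); 22 of the 32 reach 1 unit in another library too. A test of 1 ratio of the 13 counts between these libraries did not decide on a single source (chi-square test, Monte Carlo p = 0.354, 100000 resamples): it covers counting error alone, and an equal response of both clones would give 1 ratio too. A response of CC cells to palmitic acid stays open: the summed level in treated GC libraries was 0.484% of that in treated CC libraries, which leaves a response that needs both C alleles. Carried-over RNA and such a response cannot be told apart, since the 2 libraries are the whole treated CC group.

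The treated library of CC clone 3 moved furthest from its control. Its low read depth was argued against: with all libraries thinned to its depth of 9314342 reads, its SD of log2 changes was still 1.36 times the next largest (1.40 before). CC clone 1 had a slope of 0.560 on the mean of the other clones, under the GG and GC median of 0.709. CC clone 3 had 1.39, so the steep slope was not shared by both CC clones. This cannot decide on the CC genotype as the cause, since 0.560 is from 1 clone and lies within the GG and GC range of 0.524 to 1.07. By chi-square per degree of freedom, the treated library of CC clone 3 was nearer to that of GG clone 6 (20.4) than to its own control (43.4). The treated library of GG clone 6 was nearest to its own control. The cause of this nearness, a mix-up of samples included, was not tested. The state or dose of the single treated culture of CC clone 3 stays open as well and was not tested. The interaction differences of hepatocyte, cholesterol and apolipoprotein genes against CC given above shrank or reversed without this clone.

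Clones of the same genotype differed widely. Chromosome-wide dosage shifts were argued against as the main cause, since the chromosome explained 2.32% of the variance between clones (0.311% at the upper bound of the shuffled range). Read depth was argued against too, since in 8 of 8 clones the control and treated library deviated together with r above 0.5. A change of dosage of single chromosomes may still add to the differences between clones. Chromosome medians of control and treated libraries correlated at 0.877 over 176 values, with an SD of 0.0528 against at most 0.0205 in 1000 shuffles. Examples are chromosome 13 in GG clone 2 (-0.21) and chromosome 10 in GC clone 4 (-0.21). The medians are of deviations from the mean of the clones of a genotype, so the 176 values are not independent. Chromosome 13 was at 0.087 in GG clone 1 and 0.13 in GG clone 6, so a loss in GG clone 2 and gains in the others cannot be told apart. Libraries of a clone deviate together gene by gene, so the correlation alone does not show dosage. Differences that editing or growth from a single cell brought were not tested.

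For the palmitic acid response over genotypes with clone block, chance is unlikely: 1 of 100 splits, the real one, gave as many genes (real 2469, highest other 1). This is the smallest share that 100 splits can give. The splits swap labels within clones and cannot part palmitic acid from anything else that all treated cultures shared. Without block, chance cannot be excluded: 13 of 100 splits gave at least the real 6, and the highest other gave 2234, which points to a structure of the samples. The other 12 of those 13 parted 2 or 4 of the 8 pairs and kept the other clones whole, while the other 8 splits that part all 8 pairs, as the real one does, gave at most 1 gene. For the other counts the splits are too few for a share under 0.05. In GG and GC with block 1 of 4 splits gave as many (real 110 and 202, highest other 0 and 0). Without block 10 of 10 splits did in GG, in GC, in GG against GC in control and under palmitic acid, and in their interaction (real 0, highest other 0 each). The interaction with block gave 10 of 10, with real 0 and highest other 1.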

How the results depend on the processing

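The settings that left out whole clones or CC clone 3, the GG and GC clones alone, and the other choices combined with the clone block were chosen after seeing the data. Of the results that answer a comparison, 331 alternatives gave the same verdict, 89 moved and 5 reversed, and of named genes and lists 3617 were the same, 370 weaker, 12 stronger and 19 reversed; the cause was not tested except where named. A pseudocount of 0.1 gave 2 genes for palmitic acid over genotypes and 0 for both interactions with CC. With no filter, which lets near-absent transcripts in, the counts were 12 over genotypes, 16 in CC, 18 for GG against CC and 17 for GC against CC under palmitic acid, and 12 and 13 for their interactions. A filter of 5 units, which leaves MUC5AC out, gave 2 over genotypes and 0 for those other 5. A fit on only the groups compared, with fewer samples, gave 0 for the same 5. EdgeR gave 2 over genotypes and 0 for the same 5. DESeq2 gave 108 over genotypes, 1 in GG, 2 in GC, 0 in CC, 2 for GC against CC and 20 for GG against GC in control, 21 for each of GC against CC and GG against GC under palmitic acid, and 0 and 0 for the interactions with CC.

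The replicate block gave 2469 genes over genotypes, 110 in GG, 202 in GC and 301 in CC, and 7 lists in GG and 5 for GG minus GC. Of list calls it added the integrated stress response over genotypes and for GC minus CC, apolipoproteins, autophagy and hepatocyte genes in GG, autophagy and cell cycle genes in CC, and 4 lists for GG minus GC. It changed no other call. With the block, equal totals gave 199 in CC and quantile normalization 61 in GG. Leaving out a clone with the block gave 1254 (CC clone 3) to 3753 (CC clone 1) over genotypes, 0 to 24 in GG, 2 to 107 in GC and 13 to 2082 in CC. Leaving out 1 library without block gave 0 (treated CC clone 3) to 82 (treated CC clone 1) over genotypes and 1 to 2 in CC; a group left with 1 library is assumed to vary like the others. Of the 16 left-out libraries, 12 moved the count over genotypes past 1.5 times.

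Camera with an estimated correlation called 0 of the 24 lists set before the fits in all 13 comparisons. No list test left out CC clone 1 alone. With the preset correlation and without both libraries of CC clone 3, camera called 8 lists in GG, 1 in CC, 7 for GG against CC and 3 for GC against CC in control, 8 for GG against CC under palmitic acid, 5 for GC minus CC and 2 for GG minus GC; with an estimated correlation it called 0 there too. Of the lists called with all clones, the means that reversed there were cholesterol synthesis in CC (-0.082), in GC against CC in control (-0.32), for GG minus CC (0.094) and GC minus CC (0.15), oxidative phosphorylation (-0.069, GG against CC) and fatty acid synthesis (-0.10, GC against CC) in control, hepatocyte genes in GG against CC (-0.051) and GC against CC (-0.18) under palmitic acid and for GC minus CC (-0.051), and apolipoproteins for GG minus CC (-0.035) and GC against CC under palmitic acid (0.0495, with camera's direction reversed). Lists not called with all clones were not followed, though some turned as well, such as cholesterol synthesis in GG against CC in control (-0.59, adjusted p = 1.78e-08, and adjusted p = 0.301 with an estimated correlation). PNPLA3 reversed for palmitic acid without untreated CC clone 3 (-0.26) or treated CC clone 1 (-0.25; range -0.26 to 0.56), for GG against CC without untreated GG clone 6 (0.05) or untreated CC clone 1 (1.08; range -1.39 to 1.08) and for GC against CC without untreated CC clone 3 (-0.54; range -0.54 to 1.92), and ran from -1.06 to -0.64 for GG against GC. TSPO in GG against CC was -0.0039 by edgeR and ran from -0.99 (without untreated CC clone 1) to 2.98 (without untreated CC clone 3). The interactions of TF ran from -0.41 to 2.14 (GG minus CC), and those of APOA5 from -0.11 to 2.43 (GG minus CC) and -0.35 to 2.18 (GC minus CC), the lowest without treated CC clone 3. These ranges and that of PNPLA3 for palmitic acid are from the fit without block, where a left-out library leaves its partner unpaired. With block, MT1E was -0.23 without CC clone 3 (highest 0.78), MT1X 0.23 without CC clone 1 (lowest -0.55) and KRT19 -0.041 in the GG and GC clones alone. No scaling moved the median of all genes by more than 0.0384. Depth limits what can be said of PNPLA3, with 22 to 211 reads, and of the mucous transcripts, of which all but MUC5AC lie under the filter.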

Other observations

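All gene lists in this part were chosen after seeing the data, as were the genes named from them, so their tests are not independent evidence.

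Most tested genes of an actin cytoskeleton list rose under palmitic acid. Of 30 tested regulators, 20 rose and 1 fell by limma with clone block (23 up and 1 down adjusted over the list alone; median 0.39), among them the focal adhesion protein ZYX (0.65 ± 0.05, n = 8 clones), the actin bundler FSCN1 (0.69 ± 0.06) and CAP2 (0.89 ± 0.07). Camera gave an adjusted p = 1.32e-13, and adjusted p = 0.134 with an estimated correlation (0.0218 without block). Of 29 members of the activin, BMP and TGF-beta pathways, 10 rose and 3 fell (11 up and 3 down adjusted over the list alone; median 0.06), with the activin-responsive MIXL1 at 1.57 ± 0.11, the SMAD repressor SKIL at 0.89 ± 0.06 and SMAD9 at -0.75 ± 0.11. The camera adjusted p was 0.00318, and adjusted p = 0.0825 with an estimated correlation (0.304 without block). These values stand beside the 2469 genes called over genotypes with the replicate block.

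Most tested coagulation and complement genes fell, the fibrinogens among them. Of 35 tested, 1 rose and 19 fell (2 up and 22 down adjusted over the list alone; median -0.35), among them KNG1 (-2.08 ± 0.17), factor XIII subunit F13B (-1.57 ± 0.20), the growth factor activator HGFAC (-1.20 ± 0.11) and antithrombin SERPINC1 (-0.95 ± 0.09). Camera gave 1.23e-10, and adjusted p = 0.137 with an estimated correlation (0.0900 without block); F2, FGA, FGB, FGG and C3 are also on the hepatocyte list. Of 25 genes of alcohol, retinol and amino acid catabolism, 2 rose and 14 fell (2 up and 16 down adjusted over the list alone; median -0.34), among them AGXT (-1.29 ± 0.13), BHMT (-1.24 ± 0.17) and the alcohol dehydrogenase ADH4 (-1.04 ± 0.10). The camera adjusted p was 8.46e-07, and adjusted p = 0.137 with an estimated correlation (0.114 without block).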
